A study of Mus musculus with 3 samples.

How the data were processed

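Single-cell RNA sequencing of mouse mesenteric lymph node was analysed in 3 libraries, 1 per group, each made from the pooled nodes of 6 animals. Per the labels, the animals were fed orally for 4 weeks with 5 mM citrate buffer, with 1 µg ovalbumin (free OVA) or with 1 µg ovalbumin in lyso-phosphatidylserine nanoparticles (LysoPS-OVA). The nodes were digested with enzymes, dead cells were removed and 10000 cells were loaded per library on a droplet platform with 3' chemistry, per the labels' protocols. The values used are the deposited raw UMI counts per gene and barcode, made by the authors with Cell Ranger 7.2.0 against mm10, per the submitters' processing notes and the file headers. The annotation version and the intron setting behind these counts were not given in the sources used here.

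The deposited matrices hold 32285 genes. They hold 28927 barcodes for citrate buffer, 28660 for free OVA and 20873 for LysoPS-OVA, so each holds more barcodes than the cells loaded. The lowest UMI totals per barcode were 501, 500 and 500. Gene positions came from GENCODE release 21 for mouse (GRCm38/mm10), joined by Ensembl identifier, and 32158 of the 32285 genes (99.6%) had a match.

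Barcodes with at least 300 detected genes and at most 10% mitochondrial UMIs were kept. This removed 11, 1904 and 143 barcodes for few genes in citrate buffer, free OVA and LysoPS-OVA, and 2568, 3425 and 3407 for mitochondrial UMIs. Doublets were called per library with Scrublet in scanpy, with an expected rate of 0.8% per 1000 barcodes and its automatic threshold. It called 4355 doublets (16.5%) in citrate buffer, 1728 (7.41%) in free OVA and 1394 (8.05%) in LysoPS-OVA, where that rate over the deposited barcodes gives 23.1%, 22.9% and 16.7%. After removal 21993, 21603 and 15929 barcodes were left.

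The 3 libraries were clustered together on library-size scaled log values of 2000 variable genes without immunoglobulin and T cell receptor genes, with 30 principal components, 15 neighbours and Leiden resolution 1.0. Neighbours were weighted by the share of neighbours in common (Jaccard). Clusters were named from 26 marker lists: a class needed at least 3 markers more than 1 log2 above the other barcodes and a median over its markers above 0.5 log2, and the class with the highest median was taken. Clusters that met no list, shallow clusters with no marker of their class among their 10 leading genes, and clusters whose leading genes belonged to another lineage were left unnamed. Clusters that met the lists of unrelated classes were set aside as mixed. Names end in "-like" because they rest on transcripts alone. UMIs were summed per library and class and scaled by the summed UMIs of the class to CPM, and log2 ratios used a pseudocount of 10 CPM. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9.

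All 3 pairs of libraries were compared. With 1 library per group no spread between animals can be estimated, so no test of a difference and no p-value was computed. The single count of genes that differed is descriptive and rests on a log2 threshold met in 4 classes. The 95% intervals are exact binomial (Clopper-Pearson) for shares, exact Poisson for CPM, conditional binomial for folds, the log method of Katz for ratios of shares, and 2000 Poisson draws for list medians. They cover counting error only, and cells are not replicates of a treatment.

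Named genes followed a rule set before the data were examined. For each comparison and each of 4 classes (B-like, CD4 T-like without regulatory T-like, CD8 T-like, antigen-presenting myeloid-like) the rule took the 4 genes with the highest and the 4 with the lowest log2 ratio among genes at 50 CPM and 30 UMIs or more in the higher library. Immunoglobulin, T cell receptor, ribosomal, mitochondrial and haemoglobin genes and unnamed gene models were left out. For LysoPS-OVA it also took the 4 highest and 4 lowest per class against both other libraries. From gene lists, the 4 members farthest from 0 could be named, and Foxp3, Il10, Tgfb1 and Ctla4 always where measured. A few genes that these rules name are not reported here.

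The 30 gene lists were fixed at the same time: regulatory T cell and tolerance, T cell anergy and exhaustion, type 1, type 2 and type 17 effector T cell, naive and central memory lymphocyte, gut homing and residence, tolerogenic antigen-presenting cell, phosphatidylserine receptor and efferocytosis, lysophosphatidylserine receptor and metabolism, MHC class II, MHC class I, costimulation, interferon response, inflammatory cytokine and NF-kB, B cell activation, germinal centre reaction, antibody secretion, immunoglobulin constant regions, TGF-beta response, cell cycle, early response and dissociation stress, unfolded protein response and apoptosis, glycolysis and hypoxia, oxidative phosphorylation, mitochondrial genes, cholesterol and lipid handling, haemoglobin and platelet, stromal and endothelial, and epithelial. A member counted as measured at 20 CPM or more in either library, and lists with fewer than 5 measured members got no median. Each median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and was read as apart from them at percentile 97.5 or above or 2.5 or below. Those percentiles describe these libraries and are not tests. The list medians were taken in regulatory T-like and migratory dendritic cell-like barcodes as well.

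The share of T-like barcodes with a UMI of each regulatory T cell marker was taken as thinned to 1000 UMIs, with B-like barcodes as the background. It is the number expected to keep a UMI when 1000 UMIs are drawn without replacement from each barcode, rounded to a whole number, and barcodes below 1000 UMIs were left out (133 T-like in citrate buffer, 34 in free OVA and 23 in LysoPS-OVA).

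The alternatives fixed before the data were examined were 500 genes, 5% mitochondrial UMIs, doublets kept, Leiden resolutions 0.5 and 2.0, each library clustered on its own, CPM without the gene families named above, median-of-ratios size factors, the mean of per-cell CPM, pseudocounts of 1 and 50 CPM, a filter at 5 CPM, no filter, thinning to 1500 UMIs, no thinning, and T cells taken by Cd3 transcripts. The thresholds that define low-Malat1 barcodes (Malat1 under 0.5% of UMIs), low-ribosomal barcodes (ribosomal protein genes under 10%) and whole-cell-like barcodes (neither) were chosen after the data were seen, as were the alternatives restricted to whole-cell-like barcodes and to at least 1500 UMIs.

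The procedure was tested on simulated data: 15 comparisons with 200 changed genes each gave the right direction for 100% of changed genes, with intervals that covered the true fold in 88% to 100% of them. Both libraries of a comparison were drawn from 1 shared profile with counting noise only. The intervals were rescaled by the known change in total counts. A list of 12 members with 0.5 log2 added to its ratios reached percentile 100 in all 15, which so little noise nearly fixes in advance. Of the 15 unshifted lists 1 passed the upper bound, at percentile 98.2, and the largest log2 of an unchanged gene was 0.419, so smaller ratios of single genes can be counting noise in the smaller classes. Scatter between real libraries was not simulated, so these values do not tell how well a shift of this size is found here.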

Results

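Mesenteric lymph nodes, which drain the intestine, were profiled by droplet single-cell RNA sequencing after 4 weeks of oral feeding with citrate buffer, free ovalbumin (free OVA) or ovalbumin in nanoparticles that carry lyso-phosphatidylserine (LysoPS-OVA). Ovalbumin is the model food antigen, and the series asks which cells of the node bear features of tolerance. Each group is 1 library of 6 pooled animals. The citrate buffer library held 96616683 UMIs with a median of 2577 per barcode, the free OVA library 81559237 with 1492, and the LysoPS-OVA library 84089686 with 3686. After filtering, 21993, 21603 and 15929 barcodes were kept. There is no replicate, so every difference below is a difference between 1 library and another, and its 95% interval covers counting error only. The sex makeup of the pools may differ too. Of whole-cell-like B-like barcodes with transcripts of a single sex, 53.9% carried Y-linked ones in citrate buffer, 76.2% in free OVA and 87.6% in LysoPS-OVA. In CD8 T-like ones these shares were 62.4%, 84.8% and 82.1%. Whether sex makeup bears on a difference was examined only for some genes, between LysoPS-OVA and citrate buffer. For class shares and gene lists it was not tested.

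The kept barcodes differed in their Malat1 and ribosomal transcripts, and so did the libraries. Whether barcodes low in either were partial cells was examined only for low Malat1 in migratory dendritic cell-like barcodes. Malat1, a long noncoding RNA held in the nucleus, made up less than 0.5% of UMIs in 27.8% of citrate buffer barcodes (95% interval 27.3 to 28.4), 51.5% of free OVA barcodes (50.8 to 52.2) and 21.7% of LysoPS-OVA barcodes (21.1 to 22.4). Barcodes with few ribosomal protein transcripts were 21.7% in citrate buffer (21.1 to 22.2), 8.41% in free OVA (8.04 to 8.78) and 10.7% in LysoPS-OVA (10.2 to 11.2). The rest, called whole-cell-like here, were 50.5%, 40.1% and 67.6%. The median mitochondrial share of UMIs was 6.16%, 6.25% and 6.84% in the barcodes low in ribosomal transcripts and 2.91%, 2.38% and 3.55% in the whole-cell-like ones. In barcodes low in Malat1 it was 1.35%, 1.08% and 0.99%. Clusters without a clear identity held 13.6% of citrate buffer, 39.9% of free OVA and 10.5% of LysoPS-OVA barcodes, and the largest of them, led by the noncoding transcripts AY036118 and Gm42418, alone held 7.19%, 26.9% and 3.61%. Lars2 is among its leading genes too. AY036118 and Lars2 recur below among the genes that differ, and whether their ratios follow a signal of library quality was not tested.

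**Figure D1:**
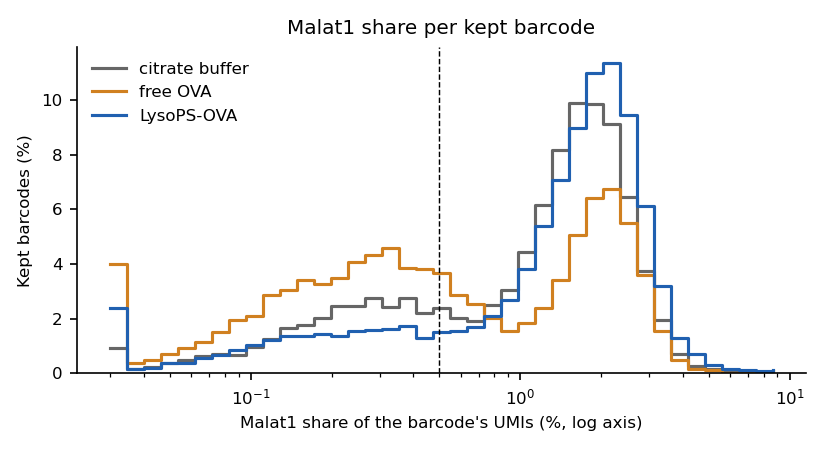
Share of each kept barcode's UMIs that are Malat1 (log axis) against the percent of kept barcodes, one line per library; the first bin gathers all lower values, and the dashed line marks 0.5%. To its left lie 27.8% of citrate buffer, 51.5% of free OVA and 21.7% of LysoPS-OVA barcodes.

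B-like barcodes (Cd79a, Fcer2a) made up 27.0% of the citrate buffer library, 21.4% of free OVA and 37.9% of LysoPS-OVA. T-like barcodes made up 36.0%, 14.1% and 35.3%, of which CD4 T-like without regulatory cells were 25.0%, 8.79% and 22.5% of kept barcodes and CD8 T-like 5.43%, 2.20% and 5.54%. Part of the CD4 T-like class is a cluster with 0 CD4 markers among its 10 leading genes and a ribosomal median of 6.01%. It held 28.5%, 16.7% and 7.48% of T-like barcodes, so the class mixes unlike parts between libraries. Of CD4 T-like barcodes 36.9%, 22.9% and 10.9% were low in ribosomal transcripts, against 1.42%, 0.42% and 0.34% of CD8 T-like ones. Whether that cluster holds T cells of other kinds was not tested. CD8 T-like barcodes were 15.1%, 15.6% and 15.7% of T-like barcodes, and 21.9%, 19.1% and 17.2% among whole-cell-like ones, where the ratio of LysoPS-OVA to citrate buffer was 0.787 (0.727 to 0.852). Antigen-presenting myeloid-like barcodes made up 12.9%, 17.8% and 10.5%, mostly dendritic cells with the migratory markers Fscn1 and Ccl22 (8.68%, 11.6% and 7.34%). An unnamed shallow cluster nearest to the migratory list held 3.08%, 7.96% and 4.08% of kept barcodes. Another, nearest to the conventional DC 2 list, held 1.84%, 4.50% and 1.88%. Neither is counted as myeloid-like in the shares and ratios given here. NK-like barcodes were 1.40%, 0.588% and 1.30%, and fibroblast-like barcodes 0.832%, 0.662% and 0.320%. Of the myeloid-like barcodes 77.7%, 87.7% and 83.9% were low in Malat1, against 0.93%, 0.41% and 1.57% of B-like ones. Of plasma-like barcodes 86.2%, 84.5% and 91.7% were low in it, and of cycling ones 87.5%, 89.7% and 86.8%. Low Malat1 thus differed between the named classes. Of unnamed barcodes 76.4%, 77.4% and 78.5% were low in it. The classes come from the same transcripts, so low-Malat1 barcodes of a cell type may be among the unnamed, and its rate per cell type was not measured. Restricting to whole-cell-like barcodes removes most barcodes of the myeloid-like, plasma-like and cycling classes.

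**Figure D2:**
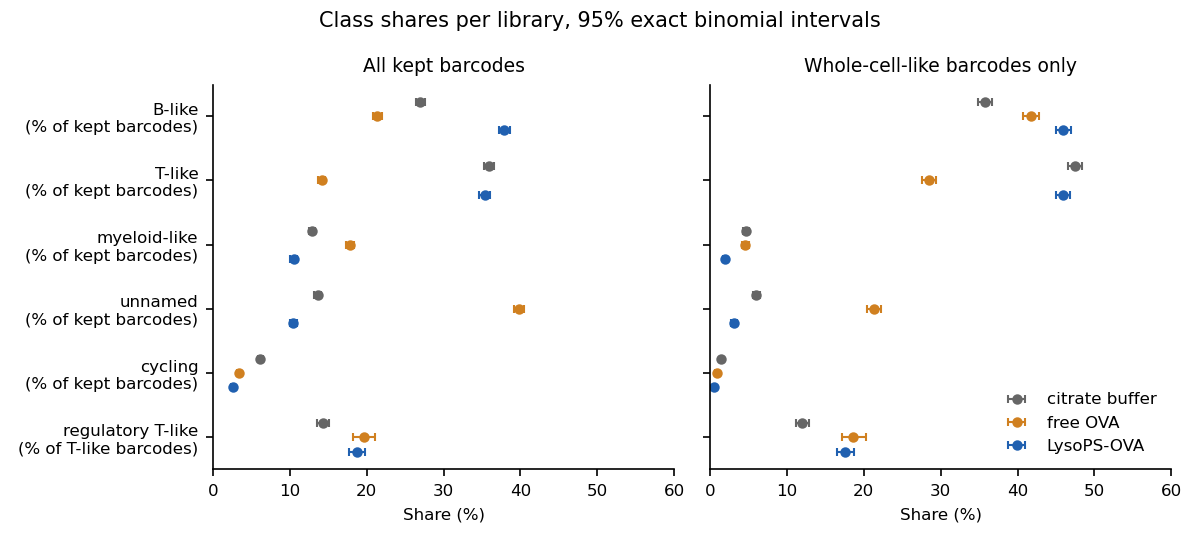
Share of each class in percent, per library, among all kept barcodes (left) and whole-cell-like barcodes only (right); points are single libraries and bars 95% exact binomial intervals. B-like barcodes lie highest in LysoPS-OVA in both panels, at 37.9% and 46.0%, and regulatory T-like barcodes lie lowest in citrate buffer in both, at 14.3% and 12% of T-like barcodes. Kept barcodes include unnamed ones, 21.3% of whole-cell-like barcodes in free OVA and 3.09% in LysoPS-OVA.

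LysoPS-OVA against citrate buffer asks how the node differed when the antigen was fed in nanoparticles rather than left out. The LysoPS-OVA library held more B-like barcodes and, among T cells, more regulatory T-like ones, whose Ctla4, Il10 and Entpd1 transcripts were higher. Genes of MHC class II antigen presentation were higher in B-like and myeloid-like barcodes. Heat shock and immediate early genes were higher in B-like, CD4, CD8, regulatory T-like and myeloid-like barcodes. Cell cycle genes and the naive lymphocyte list were lower in all of these but the CD4 T-like, where the medians (-0.28 and -0.26 log2) lay within the range of matched random lists. The naive list holds T cell genes, so a lower median in B-like and myeloid-like barcodes does not show fewer naive cells. The B-like share was 1.41 times that of citrate buffer (1.37 to 1.45), while the T-like shares differed by no more than counting error (ratio 0.983, 0.956 to 1.01). The myeloid-like share, without the unnamed clusters nearest to dendritic cell lists, was 0.816 times that of citrate buffer (0.771 to 0.863).

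Regulatory T-like barcodes were 18.8% of T-like barcodes in LysoPS-OVA (17.8 to 19.8) and 14.3% in citrate buffer (13.5 to 15.1), a ratio of 1.31 (1.22 to 1.42) that became 2.65 when each library was clustered on its own. Foxp3, the transcription factor that defines these cells, had a UMI in 2.77% of thinned T-like barcodes in LysoPS-OVA (155 of 5605, 2.35 to 3.23) and 1.92% in citrate buffer (149 of 7774, 1.62 to 2.25). With T cells taken by Cd3 transcripts the shares were 2.31% (1.88 to 2.80) and 1.66% (1.35 to 2.02), whose intervals overlap. In B-like barcodes, which should lack it, the shares were 0.133% and 0.343%; the median depths before thinning were 5101 and 3570 UMIs in T-like and 4349 and 3361.5 in B-like barcodes. Ctla4, an inhibitory receptor, was seen in 14.5% against 8.99% (B-like 1% and 1.53%). Ikzf2, which encodes Helios, was seen in 10.4% against 15.4%, but its B-like background was lower as well (1.25% and 4.89%). Gpr83 was seen in 1.96% against 3.27%, with a lower background too (0.067% and 0.326%). The intervals overlapped for Itgb8, an integrin chain that activates TGF-beta (1.25% and 0.823%), Il2ra (4.16% and 4.44%), Tnfrsf4 (2.82% and 2.79%), Tnfrsf18 (6.73% and 6.14%), Tnfrsf9 (1.73% and 1.75%) and Lrrc32 (0.143% and 0.283%). Overlap of separate intervals does not show that the shares are equal. Capg, at 5.34% and 4.91%, lay below its B-like background of 19.0% and 15.8%.

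**Figure D3:**
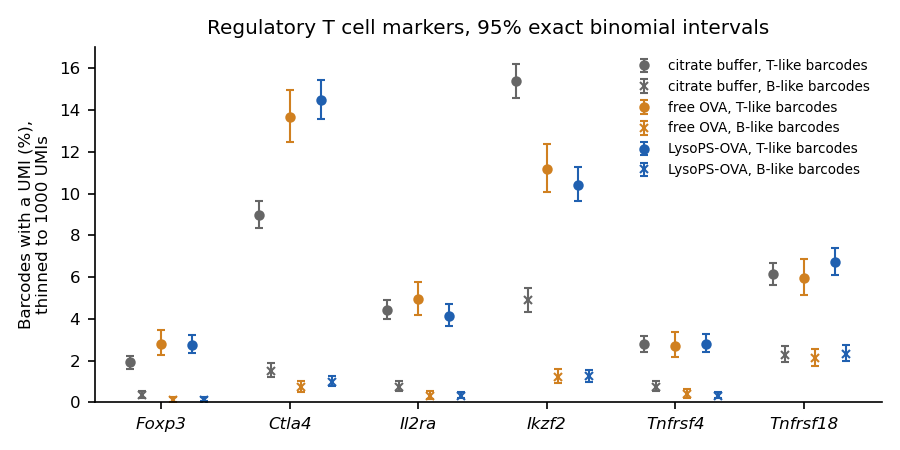
Percent of T-like (circles) and B-like (crosses) barcodes with a UMI of 6 regulatory T cell markers after thinning to 1000 UMIs, per library, with 95% exact binomial intervals. Ctla4 in T-like barcodes stands at 8.99% in citrate buffer, 13.7% in free OVA and 14.5% in LysoPS-OVA, and Ikzf2 at 15.4%, 11.2% and 10.4%.

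Within regulatory T-like barcodes (1056 in LysoPS-OVA, 1131 in citrate buffer) the regulatory T cell list had 13 members higher and 6 lower, with a median of 0.05 log2 that was not apart from matched random lists. Of these barcodes 41.8% in citrate buffer, 22.7% in free OVA and 16.5% in LysoPS-OVA were low in ribosomal transcripts. The list's farthest members were functional ones: Il10, an anti-inflammatory cytokine, was 2.27 times as high (1.64 to 3.19), Entpd1, the ectonucleotidase CD39, 2.25 times (1.85 to 2.75), Lag3, an inhibitory receptor, 1.71 times (1.34 to 2.19) and Ctla4 1.58 times (1.51 to 1.65); among whole-cell-like barcodes the folds were 2.01, 2.55, 1.45 and 1.34. Foxp3 itself was 1.33 times as high (1.18 to 1.49), and Tgfb1 did not differ (1.04, 0.920 to 1.19). The interferon response list was higher, with 15 members up and 3 down (median 0.19 log2), led by Ifit1 (1.76-fold), Iigp1 (1.71-fold), Ly6a (1.48-fold) and Ifi47 (1.37-fold). The tolerogenic list was higher as well (0.15 log2, 6 up and 3 down), with Pdcd1lg2, which encodes the inhibitory ligand PD-L2, at 1.5-fold. The naive list was lower (-0.43 log2): Satb1 was 0.579 times as high and Igfbp4 0.561, although Il7r was 1.77 times as high. The anergy list (-0.24 log2) and the type 17 list (-0.15 log2) were not apart from matched lists, and the type 1 list (0.04 log2) was not either, with Cxcr3 at 1.44-fold and Ccl5 at 0.567-fold (B-like 0.514). P2ry10, a lysophosphatidylserine receptor, was 1.49 times as high (1.34 to 1.67), but its list as a whole (-0.10 log2) was not apart.

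Of B-like barcodes 32.1% in citrate buffer, 21.4% in free OVA and 16.5% in LysoPS-OVA were low in ribosomal transcripts. In B-like barcodes the MHC class II list had 11 members higher and 1 lower (median 0.20 log2): H2-Eb1 was 1.36 times as high (1.34 to 1.38), the invariant chain Cd74 1.34 times, H2-Ab1 1.28 times and H2-Aa 1.26 times. The costimulation list was higher in all 5 measured members (0.18 log2), led by Cd86 at 1.60-fold (1.52 to 1.69), and so was B cell activation (0.09 log2, 8 up and 3 down) with Nfkbid (1.62-fold), Irf4 (1.47-fold) and Cd69 (1.42-fold). Among gut homing genes (0.14 log2) the integrin Itgb7 was 1.42 times as high. The highest single genes were Nr3c2, the mineralocorticoid receptor (5.10-fold, 4.53 to 5.76), Vmn2r96, a gene annotated as a vomeronasal receptor (4.75-fold, 4.45 to 5.07), and the heat shock proteins Hsph1 (3.15-fold) and Dnaja1 (2.83-fold). The lowest were Agbl1 (0.251 times), the Polycomb methyltransferase Ezh2 (0.335), the T cell factor Tcf7 (0.356) and Xist, the RNA that silences 1 X chromosome in females (0.369), while summed Y-linked genes were 1.49 times as high among whole-cell-like barcodes (1.43 to 1.55). Against both other libraries the highest were Hsp90aa1, Hsph1, Tespa1 and Ankrd33b (1.76, 3.15, 1.62 and 2.56 times citrate buffer) and the lowest Def8, AY036118, Cmss1 and Camk2b (0.450, 0.541, 0.581 and 0.577 times). Immunoglobulin constant regions were higher (0.12 log2), with Ighg3 at 2.22-fold and Igha at 0.512, antibody secretion genes (-0.07 log2) were not apart, and neither was MHC class I. When each library was clustered on its own the B cell activation median was -0.01 log2, and without a filter on low counts the gut homing median was -0.07 and that of the tolerogenic list in regulatory T-like barcodes -0.01.

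In CD4 T-like barcodes the all-gene median was -0.16 log2, and in citrate buffer 36.9% of these barcodes were low in ribosomal transcripts against 10.9% in LysoPS-OVA. Against that shift the highest genes were Vmn2r96 (3.48-fold, 3.05 to 3.99; chromosome 17, 18573151 to 18616003), H2-Q7, a nonclassical MHC class I gene (2.5-fold, 2.38 to 2.63; chromosome 17 from 35439155, ENSMUSG00000060550), Hsph1 (2.48-fold) and Dnaja1 (2.32-fold). The sum of 6 H2-Q genes, whose sequences are nearly alike, was 2.07 times as high among whole-cell-like barcodes (1.98 to 2.17). The lowest were the metalloprotease Adam19 (0.261 times, 0.319 among whole-cell-like barcodes), Ikzf2 (0.287, and 0.402; B-like 0.256), Ezh2 (0.308) and Xist (0.353). H2-Q7, Hsp90aa1, Klf6 and the tetraspanin Cd9 were higher against both other libraries (2.5, 1.72, 2.20 and 1.71 times citrate buffer), and the chemokine Ccl5, AY036118, Cmss1 and Lars2 lower (0.382, 0.462, 0.564 and 0.657 times). In CD8 T-like barcodes Vmn2r96 (5.32-fold), H2-Q7 (2.45-fold), Hsph1 (2.32-fold) and Dnajb1 (2.24-fold) were highest, and Ikzf2 (0.187 times), Cd7 (0.304), Ezh2 (0.384) and Itgae, the integrin chain CD103 of gut-resident T cells (0.418), lowest. There Cdc14b was also higher against both (1.95 times citrate buffer), and Dnmt1, the interferon-induced Ifi27l2a, AY036118 and Cmss1 lower (0.674, 0.638, 0.570 and 0.610 times). The TGF-beta response list was lower in CD8 T-like barcodes (-0.27 log2, 8 of 9 members), and the mitochondrial genes were higher (0.27 log2, all 13).

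The early response and stress list was higher in 5 classes: its median was 0.74 log2 in B-like barcodes (13 up, 1 down), 0.59 in regulatory T-like, 0.49 in CD4, 0.26 in CD8 and 0.26 in myeloid-like ones. In B-like barcodes Fosb was 3.88 times as high, Fos 2.75 times, the co-chaperone Dnajb1 2.74 times and Jun 1.96 times. Cell cycle genes were lower, with medians of -0.40 log2 in B-like, -0.51 in regulatory T-like and -0.44 in myeloid-like barcodes, where all 12 members were lower. Top2a was 0.266 times as high in B-like and 0.182 in regulatory T-like barcodes, at levels of 7.55 and 12.5 CPM, and the cycling class itself held 2.62% of LysoPS-OVA and 6.13% of citrate buffer barcodes. In T cells the transcripts of other cell types were lower too: MHC class II genes had medians of -0.69 log2 in CD4 and -0.42 in CD8 T-like barcodes, and immunoglobulin constant regions -1.28 and -0.67. In B-like barcodes the naive list was lower (-0.27 log2) through the T cell genes Tcf7, Igfbp4 (0.379 times) and Lef1 (0.488 times), while Klf2, a factor of resting lymphocytes, was 1.54 times as high.

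In myeloid-like barcodes (1673 and 2832), where the all-gene median was -0.10 log2, MHC class II genes were higher in 11 of 12 members (0.28 log2): H2-Ab1 was 1.48 times as high (1.43 to 1.52), H2-DMb1 1.37 times, H2-Eb1 1.35 times and Cd74 1.34 times. The tolerogenic list was not apart (-0.12 log2, and 0.02 with the mean of per-cell CPM). Among its members Aldh1a2, the enzyme with which gut dendritic cells make retinoic acid, was 0.653 times as high (0.595 to 0.715), Ebi3 0.618 times and Cd274, which encodes PD-L1, 0.818 times. The highest genes were Vmn2r96 (6.27-fold), Ccl6 (3.85-fold, 1.28 among whole-cell-like barcodes), Cpne8 (3.74-fold, and 6.41 there) and H2-M2 (2.59-fold), and the lowest Lrmda (0.407 times, and 0.620 there), Rasgrp2 (0.430), Top2a (0.434) and Igfbp4 (0.445). Lrmda is a leading gene of the conventional DC 2-like cluster, which held 2.39% of LysoPS-OVA and 4.10% of citrate buffer myeloid-like barcodes. Ankrd33b, Slc22a23 and Pam were higher against both other libraries (2.10, 2.05 and 2.05 times citrate buffer), and Cmss1, AY036118, Aldh1a2 and Tln1 lower (0.613, 0.639, 0.653 and 0.689 times). The naive list was lower (-0.50 log2, all 11 members), as were immunoglobulin constant regions (-0.52 log2). Igfbp4, a member of the naive list, is a leading gene of a CD4 T-like cluster. How far these medians reflect transcripts of other cell types was not tested. Among receptors for phosphatidylserine, Cd36 was 1.33 times as high and the bridging protein Mfge8 0.459 times, and the list was not apart (-0.03 log2). The same held in this class for germinal centre (0.09 log2), inflammatory (-0.08), cholesterol (-0.18) and unfolded protein response genes (-0.12), and for glycolysis and oxidative phosphorylation. Below 5 measured members in every class were the type 2 effector list (3 at most), stromal and endothelial (3), haemoglobin and platelet (2) and epithelial (0), so none of these has a median. The myeloid-like share ratio was 0.43 among whole-cell-like barcodes, and the CD4 T-like share ratio (0.901) reached 1 or more under 4 alternatives, while the plasma-like ratio (1.32) fell to 0.58 among whole-cell-like barcodes.

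LysoPS-OVA against free OVA compares feeding of the same 1 µg of antigen with and without the nanoparticle. The sex makeup of these pools may differ as well, and its part in this comparison was not tested. Of all kept barcodes, the LysoPS-OVA library held more B-like and T-like and fewer myeloid-like ones. The regulatory T-like share of T cells and the Foxp3 share did not differ, but regulatory T-like barcodes carried more Il10, Lag3 and interferon response transcripts. H2-Q7 and the heat shock gene Hsp90aa1 were higher in CD4 and CD8 T-like barcodes, and Aldh1a2 was lower in myeloid-like barcodes. The B-like share was 1.77 times as high (1.72 to 1.83), the T-like share 2.5 times (2.41 to 2.60) and the myeloid-like share 0.591 times (0.560 to 0.623); regulatory T-like barcodes were 18.8% and 19.6% of T-like ones (ratio 0.956, 0.873 to 1.05). Foxp3 was seen in 2.77% and 2.82% of thinned T-like barcodes (B-like 0.133% and 0.109%), a difference not detectable at this depth, and Ctla4 in 14.5% and 13.7%.

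In regulatory T-like barcodes Il10 was 7.87 times as high (4.27 to 16.1), from 25.8 CPM in LysoPS-OVA and 3.28 CPM in free OVA (11.4 in citrate buffer), Lag3 was 2.05 times as high and the galectin Lgals1 1.71 times, while Foxp3 (0.991), Tgfb1 (0.962) and Ctla4 (1.04, 0.992 to 1.08) did not differ beyond counting error. All 18 measured interferon response genes were higher (median 0.29 log2), among them Ifit1 (1.73-fold), Ifi47 (1.48-fold), Gbp2 (1.45-fold) and Zbp1 (1.40-fold). A T-like cluster led by Ifit1 and Isg15, which held 1.94% of T-like barcodes in LysoPS-OVA and 2.56% in free OVA, lies outside the regulatory T-like class. The tolerogenic list was higher (0.23 log2) with Pdcd1lg2 at 1.65-fold, the type 17 list also (0.24 log2), and the chemokine Ccl5 was 0.244 times as high, at 82.5 against 338 CPM. Ccl5 is a leading gene of the dendritic cell clusters, at 12710 and 12000 CPM in migratory dendritic cell-like barcodes, and in B-like barcodes it was 0.608 times as high. In the other T cells H2-Q7 was 1.98 times as high in CD4 and 1.72 times in CD8 T-like barcodes, the scavenger receptor Colec12 2.21 and 2.06 times, and Hsp90aa1 1.62 and 1.54 times. Tnfaip3, which restrains NF-kB, and Cd9 were highest in CD4 T-like barcodes as well (1.78-fold and 1.84-fold), and Slc25a40 in CD8 T-like ones (1.89-fold). AY036118 (0.271 and 0.305 times) and Def8 (0.257 and 0.269) were lowest in both, with Ccl5 (0.337) and Mid1 (0.440) in CD4 and H2-T23, which encodes the nonclassical MHC molecule Qa-1 (0.483), and Ly6a (0.541) in CD8 T-like barcodes. The regulatory T cell list was higher in CD4 T-like barcodes (0.17 log2), with Ctla4 at 1.32-fold.

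In B-like barcodes Colec12 (2.22-fold), Tespa1 (1.72-fold), Hsph1 (1.71-fold) and Hsp90aa1 (1.66-fold) were highest and AY036118 (0.331 times), Fosb (0.418), Def8 (0.469) and Camk2b (0.498) lowest. The stress list was higher by a median of 0.15 log2 in B-like and 0.28 in CD4 T-like barcodes, with Hspa8 at 1.49-fold in B-like ones, although Egr1 was 0.665 times as high there. B cell activation was higher (0.17 log2) with Batf (1.37-fold) and Cd86 (1.34-fold), while MHC class I was lower (-0.16 log2) with Tap1 at 0.746 and H2-D1 at 0.803 times. Oxidative phosphorylation (0.15 log2, 15 of 16 members), mitochondrial genes (0.36 log2) and glycolysis (0.14 log2, Gapdh 1.35-fold) were higher in B-like barcodes. In myeloid-like barcodes the all-gene median was 0.17 log2. The highest genes there were Siglech, a lectin of plasmacytoid dendritic cells (7.22-fold), Grm8 (5.63-fold), Megf11 (4.99-fold, and 1.81 among whole-cell-like barcodes) and Dscam (3.99-fold, and 1.78), and the lowest AY036118 (0.228 times), Def8 (0.286), Jchain (0.313, but 2.13 among whole-cell-like barcodes) and Gclc, an enzyme of glutathione synthesis (0.432). Siglech and Grm8 lead the plasmacytoid cluster, which held only 21 of the 1673 LysoPS-OVA and 19 of the 3841 free OVA myeloid-like barcodes, and 255 of the 279 Siglech UMIs in LysoPS-OVA lay in whole-cell-like barcodes, of which 8 were in that cluster. Dscam and Megf11 are leading genes of the conventional DC 2-like cluster (2.39% and 1.17% of myeloid-like barcodes) and of a small migratory cluster (2.99% and 1.48%), which Slc22a23 leads as well. Of the genes that differed against both libraries, Vmn2r96 (2.89-fold), Pam (3.06-fold), Slc22a23 (2.39-fold) and Ankrd33b (2.12-fold) were higher than in free OVA. Among whole-cell-like barcodes Slc22a23 was 1.61-fold and Vmn2r96 1.84-fold, and the intervals of Pam (1.40, 0.967 to 2.02) and Ankrd33b (1.32, 0.941 to 1.84) included 1. Aldh1a2 (0.690 times) and Tln1 (0.696, and 0.902 among whole-cell-like barcodes) were lower. The unfolded protein response list was lower (-0.26 log2), the anergy list higher (0.62 log2, and 0.08 among whole-cell-like barcodes; Dgka 1.76-fold, and 1.06), the inflammatory list higher (0.43 log2; Nfkbiz 2.38-fold, Nfkb1 1.84-fold), and MHC class II (0.18 log2) turned to -0.04 with median-of-ratios scaling. Among whole-cell-like barcodes the B-like ratio was 1.1 and the T-like ratio 1.61, and with at least 1500 UMIs the myeloid-like ratio was 0.33. Unnamed barcodes were 21.3% of whole-cell-like ones in free OVA and 3.09% in LysoPS-OVA. Without unnamed and mixed barcodes the B-like order turned: 3613 of 6764 whole-cell-like barcodes in free OVA and 4949 of 10406 in LysoPS-OVA were B-like. Directions were lost for B cell activation in B-like barcodes with each library clustered on its own (-0.08 log2), for the regulatory T cell list in CD4 T-like barcodes with a filter at 5 CPM (-0.04), and without a filter on low counts for the type 17 (-0.04) and tolerogenic (-0.04) lists in regulatory T-like barcodes and for anergy in myeloid-like ones (0.00).

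Free OVA against citrate buffer asks how the antigen alone, without particles, differed from none. The regulatory T-like share of T cells and its Ctla4 and Entpd1 transcripts were higher in free OVA while its Il10 transcript was lower, and the early response and stress list was higher in B-like and T cell classes. T-like barcodes were much fewer in this library, and plasma-like, migratory dendritic cell-like and conventional DC 1-like barcodes more frequent. Cell cycle and naive genes were lower in regulatory T-like barcodes, and cell cycle and glycolysis genes in B-like ones. The regulatory T-like share was 19.6% (18.2 to 21.1) against 14.3%, a ratio of 1.37 (1.25 to 1.5) that became 2.78 with each library clustered on its own, and Foxp3 was seen in 2.82% (85 of 3017, 2.26 to 3.47) against 1.92% of thinned T-like barcodes, with B-like backgrounds of 0.109% and 0.343%. T-like barcodes were 0.393 times as frequent (0.378 to 0.408), myeloid-like 1.38 times (1.32 to 1.44), conventional DC 1-like 1.88 times (1.67 to 2.10) and migratory dendritic cell-like 1.34 times (0.897 among whole-cell-like barcodes). Plasma-like barcodes were 2.10 times as frequent (1.71 to 2.57), and 3.28 times (1.84 to 5.85) among whole-cell-like barcodes, from 41 and 16. Barcodes named conventional DC 2-like (0.395, 0.280 to 0.557) and plasmacytoid DC-like (0.352, 0.209 to 0.592) were fewer. The unnamed shallow cluster nearest to the conventional DC 2 list held 4.50% of free OVA and 1.84% of citrate buffer barcodes. Fewer conventional DC 2 cells as a whole are thus not shown.

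In regulatory T-like barcodes Entpd1 was 2.30 times as high (1.86 to 2.85), Itgb8 1.58 times, Ctla4 1.52 times (1.45 to 1.60) and Foxp3 1.34 times, while Ikzf2 was 0.692 times as high (B-like 0.241) and Tgfb1 did not differ (1.09, 0.941 to 1.25). Il10 was below the 20 CPM asked of list members in both libraries, at 3.28 CPM in free OVA (1.64 to 5.87) and 11.4 CPM in citrate buffer (8.47 to 15). Ccl5 was 2.33 times as high (B-like 0.846) and the costimulatory ligand Cd86 1.82 times. Naive genes were lower (-0.50 log2; Lef1 0.561 times, Satb1 0.543) and so were cell cycle genes (-0.78 log2, all 9). In CD4 T-like barcodes, where the all-gene median was -0.11 log2, Dnajb1 (2.37-fold), H2-T23 (2.19-fold) and Ust (1.87-fold) were among the highest and Ikzf2 (0.237 times, B-like 0.241), Adam19 (0.260), the ATP receptor P2rx7 (0.392) and Ezh2 (0.400) lowest. The interferon list was lower there (-0.25 log2, with Stat2 at 0.599 and Isg15 at 0.644 times), as was the tolerogenic list (-0.31 log2). The interferon direction was not kept at Leiden resolution 0.5 or 2.0. A T-like cluster led by Ifit1 and Isg15 lies outside the CD4 T-like class. It held 2.56% of T-like barcodes in free OVA and 1.16% in citrate buffer, so a lower level in T cells as a whole is not shown. In CD8 T-like barcodes H2-T23 (2.60-fold), Def8 (2.39-fold), Dnajb1 (2.20-fold) and Ust (2.19-fold) were highest and Ikzf2 (0.159 times), Ezh2 (0.351), Xist (0.366) and Itgae (0.369) lowest, and the inflammatory list was lower in all 6 members (-0.28 log2). Of whole-cell-like barcodes with transcripts of a single sex, 84.8% of CD8 T-like ones carried Y-linked transcripts in free OVA and 62.4% in citrate buffer, and 81.4% and 63.0% of myeloid-like ones.

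In B-like barcodes Fosb (9.27-fold, 7.72 to 11.2), Nr3c2 (7.13-fold, 6.34 to 8.04), Vmn2r96 (3.23-fold) and Fos (2.57-fold) were highest and Tcf7 (0.198 times), Agbl1 (0.280), Lef1 (0.385) and Zeb2 (0.441) lowest. The stress list was higher (0.45 log2), as in CD4 (0.28), CD8 (0.13) and regulatory T-like barcodes (0.33), MHC class II modestly so (0.14 log2; H2-Eb1 1.33-fold), and the regulatory T cell list by 0.18 log2 over 5 measured members, of which Entpd1 was 1.26-fold. Lower lists were cell cycle (-0.58 log2), glycolysis (-0.31 log2; Pkm 0.668 and Pgk1 0.705 times), mitochondrial genes (-0.27 log2) and oxidative phosphorylation (-0.16 log2, 14 of 16 members). In myeloid-like barcodes, where the all-gene median was -0.29 log2, Cpne8 (4.26-fold), Jchain (2.81-fold, but 0.333 times among whole-cell-like barcodes), AY036118 (2.80-fold) and H2-T23 (2.74-fold) were highest, and Grm8 (0.202 times), Xist (0.208), the sodium-calcium exchanger Slc8a1 (0.259) and Dpp10 (0.272) lowest. Of these Grm8, Xist, Slc8a1 and Dpp10 were at 0.392, 0.321, 0.367 and 0.524 among whole-cell-like barcodes. Slc8a1 leads the conventional DC 2-like cluster, which held 1.17% of free OVA and 4.10% of citrate buffer myeloid-like barcodes, and Grm8 the plasmacytoid cluster, which held 0.495% and 1.94%. Gut homing genes were lower (-0.64 log2, and -0.30 among whole-cell-like barcodes; Ccr9 0.313 times, and 0.584), and Il4i1, an amino acid oxidase that dampens T cells, was 1.44 times as high. The B-like ratio (0.793) turned to 1.17 and the myeloid-like ratio to 0.98 among whole-cell-like barcodes, where 41.7% of free OVA and 35.7% of citrate buffer barcodes were B-like, and the T-like ratio was 0.6 there. With each library clustered on its own the CD4 T-like interferon median was 0.02 log2, and without a filter on low counts the median of the regulatory T cell list in B-like barcodes was -0.10.

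**Figure D4:**
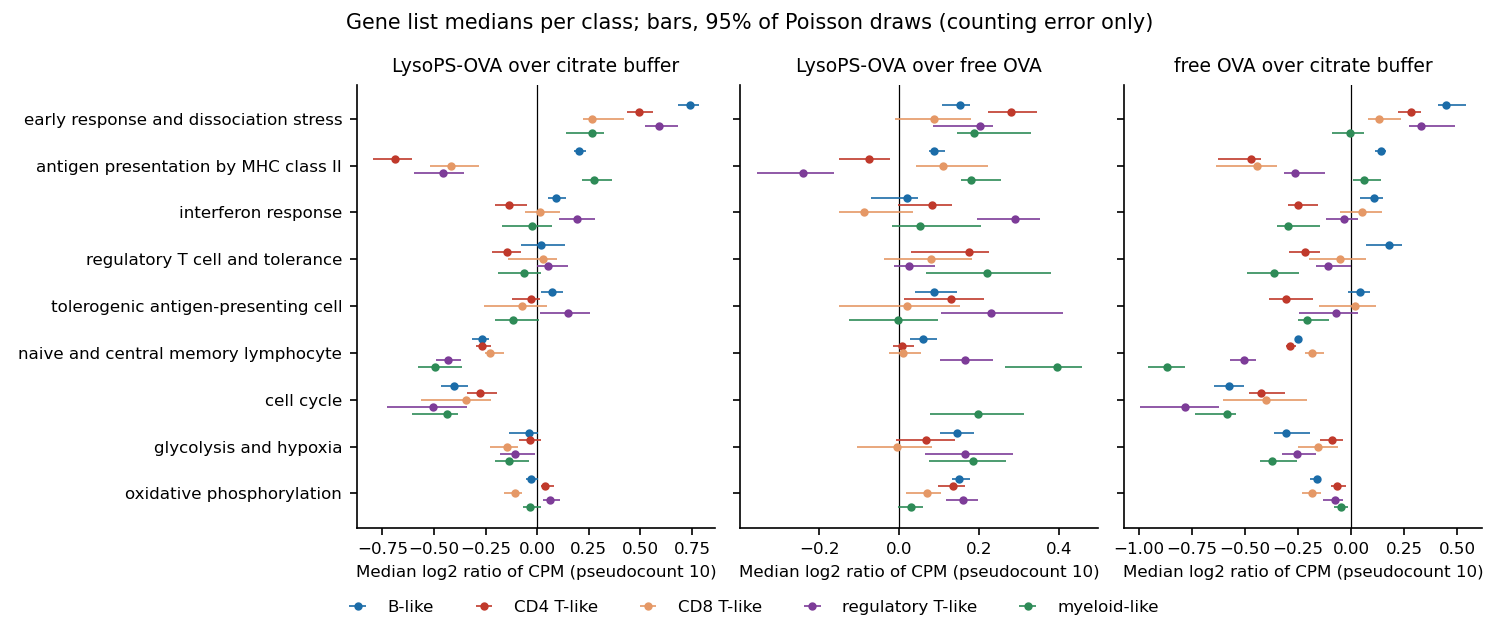
Median log2 ratio of CPM of 9 gene lists in 5 classes for the 3 comparisons (the x axes differ in range); bars hold 95% of 2000 Poisson draws and cover counting error only. The stress list lies highest in B-like barcodes for LysoPS-OVA over citrate buffer, at 0.74, and the interferon list in regulatory T-like barcodes lies at 0.19, 0.29 and -0.03.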

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

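The alternatives restricted to whole-cell-like barcodes and to at least 1500 UMIs were chosen after the data were seen; the others were fixed before. A reversal is counted only for values whose main interval lay on 1 side of no difference, for list medians with a percentile apart from matched lists. Of 46 such share ratios 37 never reversed, of 102 list medians 84 and of 141 gene folds 139. List medians of migratory dendritic cell-like barcodes are outside these counts. Of the values without such a direction, 10 of 11 share ratios and 140 of 220 list medians lay on the other side of no difference under at least 1 setting. Where a value changed, the cause was not tested. Some settings gave no value for a result, because a class or enough measured list members were missing: 48 of 57 share ratios had a value with at least 500 genes and with each library clustered on its own, and 54 with doublets kept and at Leiden resolution 0.5, and at least 317 of 322 list medians had one in every setting. With 1 library per group, depth limits the smaller classes most: no setting can replace a second library. Ratios and medians below are LysoPS-OVA over citrate buffer, LysoPS-OVA over free OVA and free OVA over citrate buffer.

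With at least 500 genes the share ratios of B-like barcodes were 1.47, 1.35 and 1.09 (the last reversed from 0.793), of T-like 1.12, 1.94 and 0.58, and of antigen-presenting myeloid-like 0.66, 0.45 and 1.46. The regulatory T-like share of T-like cells was 1.17 for LysoPS-OVA over citrate buffer and 1.23 for free OVA over citrate buffer. Reversed were CD4 T-like, LysoPS-OVA over citrate buffer (1.08), germinal centre B-like, LysoPS-OVA over free OVA (0.74) and free OVA over citrate buffer (1.35), oxidative phosphorylation in CD4 T-like, LysoPS-OVA over citrate buffer (-0.02), and the regulatory T cell and tolerance list in CD4 T-like, LysoPS-OVA over free OVA (0.00).

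With at most 5% mitochondrial UMIs B-like ratios were 1.47 for LysoPS-OVA over citrate buffer and 0.83 for free OVA over citrate buffer, T-like ratios 1.09 for LysoPS-OVA over citrate buffer and 2.79 for LysoPS-OVA over free OVA, the regulatory T-like share of T-like cells 1.19 for LysoPS-OVA over citrate buffer, and the tolerogenic list in antigen-presenting myeloid-like -0.28 for free OVA over citrate buffer. For LysoPS-OVA over citrate buffer, CD4 T-like (1.12), plasma-like (1.0), and oxidative phosphorylation in CD4 T-like (-0.07) and in regulatory T-like (-0.07) reversed.

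With doublets kept B-like ratios were 1.51 for LysoPS-OVA over citrate buffer and 0.85 for free OVA over citrate buffer, T-like 1.02 for LysoPS-OVA over citrate buffer, and antigen-presenting myeloid-like 0.56 for LysoPS-OVA over free OVA and 1.49 for free OVA over citrate buffer; the tolerogenic list in antigen-presenting myeloid-like was 0.11 for LysoPS-OVA over free OVA. Germinal centre B-like reversed for LysoPS-OVA over free OVA (0.88) and free OVA over citrate buffer (1.37), the regulatory T cell and tolerance list in CD4 T-like for LysoPS-OVA over free OVA (-0.01), and immunoglobulin constant regions in antigen-presenting myeloid-like for LysoPS-OVA over citrate buffer (0.02).

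With each library clustered on its own the B-like ratios were 1.05, 1.41 and 0.74. For LysoPS-OVA over citrate buffer T-like was 1.1, antigen-presenting myeloid-like 0.91, the regulatory T-like share of T-like cells 2.65 and the regulatory T cell and tolerance list in regulatory T-like 0.17. For free OVA over citrate buffer these were 0.44, 1.61, 2.78 and -0.17, and MHC class II in antigen-presenting myeloid-like 0.00. Reversed were CD4 T-like, LysoPS-OVA over citrate buffer (1.0), regulatory T-like of kept cells, free OVA over citrate buffer (1.22), B cell activation in B-like, LysoPS-OVA over citrate buffer (-0.01) and LysoPS-OVA over free OVA (-0.08), interferon response in B-like, free OVA over citrate buffer (-0.15), oxidative phosphorylation in CD4 T-like, LysoPS-OVA over citrate buffer (-0.05), the tolerogenic list in CD4 T-like, LysoPS-OVA over free OVA (-0.01), and interferon response in CD4 T-like, free OVA over citrate buffer (0.02).

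Among whole-cell-like barcodes only, B-like ratios were 1.29, 1.1 and 1.17 (the last reversed) and antigen-presenting myeloid-like ratios 0.43, 0.43 and 0.98 (the last reversed). T-like was 1.61 for LysoPS-OVA over free OVA and 0.60 for free OVA over citrate buffer, and the regulatory T-like share of T-like cells 1.47 for LysoPS-OVA over citrate buffer and 1.55 for free OVA over citrate buffer. In antigen-presenting myeloid-like the tolerogenic list was 0.06 for LysoPS-OVA over citrate buffer and -0.02 for free OVA over citrate buffer, and MHC class II 0.46 for LysoPS-OVA over citrate buffer and 0.29 for LysoPS-OVA over free OVA. Reversed were germinal centre B-like, LysoPS-OVA over free OVA (0.84), migratory or CCR7-high DC-like, free OVA over citrate buffer (0.90), plasma-like, LysoPS-OVA over citrate buffer (0.58), oxidative phosphorylation for LysoPS-OVA over citrate buffer in CD4 T-like (-0.14) and regulatory T-like (-0.13), and in antigen-presenting myeloid-like, LysoPS-OVA over free OVA, the naive list (-0.05), gut homing (-0.16) and Jchain (0.74 log2; -1.13 for free OVA over citrate buffer).

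With at least 1500 UMIs B-like ratios were 1.47, 1.24 and 1.19 (the last reversed), T-like 1.02, 1.78 and 0.58, antigen-presenting myeloid-like 0.58, 0.33 and 1.76, and MHC class II in antigen-presenting myeloid-like 0.15 for LysoPS-OVA over free OVA. Germinal centre B-like, LysoPS-OVA over free OVA (0.96) and plasma-like, LysoPS-OVA over citrate buffer (0.80) reversed.

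At Leiden resolution 2.0, for LysoPS-OVA over citrate buffer, T-like was 1.06, antigen-presenting myeloid-like 0.95 and the regulatory T-like share of T-like cells 1.2; for free OVA over citrate buffer T-like was 0.41, antigen-presenting myeloid-like 1.65, and in the latter the tolerogenic list -0.26 and MHC class II 0.00. For LysoPS-OVA over citrate buffer CD4 T-like (1.02), migratory or CCR7-high DC-like (1.01) and oxidative phosphorylation in CD4 T-like (-0.01) reversed, as did interferon response in CD4 T-like for free OVA over citrate buffer (0.00). At Leiden resolution 0.5 antigen-presenting myeloid-like was 0.91 for LysoPS-OVA over citrate buffer and 1.61 for free OVA over citrate buffer, with the tolerogenic list at -0.25 there, and interferon response in CD4 T-like, free OVA over citrate buffer, reversed (0.04).

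With no filter on low counts these reversed: gut homing in B-like, LysoPS-OVA over citrate buffer (-0.07) and free OVA over citrate buffer (-0.07), the regulatory T cell and tolerance list in B-like, free OVA over citrate buffer (-0.10), the tolerogenic list in CD4 T-like, LysoPS-OVA over free OVA (-0.02), anergy in antigen-presenting myeloid-like, LysoPS-OVA over free OVA (0.00), and in regulatory T-like the tolerogenic list, LysoPS-OVA over citrate buffer (-0.01) and LysoPS-OVA over free OVA (-0.04), and type 17, LysoPS-OVA over free OVA (-0.04). With a filter at 5 CPM the tolerogenic list in antigen-presenting myeloid-like was -0.33 for free OVA over citrate buffer, and reversed were, for free OVA over citrate buffer in B-like, the regulatory T cell and tolerance list (-0.27) and gut homing (-0.02), and for LysoPS-OVA over free OVA the regulatory T cell and tolerance list in CD4 T-like (-0.04) and type 17 in regulatory T-like (-0.04).

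With the mean of per-cell CPM, the tolerogenic list in antigen-presenting myeloid-like was 0.02 for LysoPS-OVA over citrate buffer, MHC class II there 0.21 and, for LysoPS-OVA over free OVA, 0.15, and the regulatory T cell and tolerance list in regulatory T-like 0.23 and 0.10. With median-of-ratios size factors, MHC class II in antigen-presenting myeloid-like was 0.38, -0.04 and 0.43, and the tolerogenic list there -0.20 for LysoPS-OVA over free OVA and 0.15 for free OVA over citrate buffer. Neither setting reversed a called median; they moved 84 of 318 and 148 of 317.

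The share of T-like barcodes with a Foxp3 UMI, thinned to 1500 UMIs, was 3.84% in LysoPS-OVA, 2.63% in citrate buffer and 3.93% in free OVA, with no thinning 8.49%, 5.21% and 9.18%, and with T cells by Cd3 gate 2.31% (1.88 to 2.80), 1.66% (1.35 to 2.02) and 2.78% (2.25 to 3.39), where the intervals of LysoPS-OVA and citrate buffer overlap. CPM without the excluded gene families, and pseudocounts of 1 and 50, reversed 0 of 322 medians and 0 of 141 gene folds; they moved 95, 30 and 69 medians and 28, 66 and 121 folds.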

Other observations

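Of the tests given here, those of low-ribosomal barcodes, of Xist against Y-linked genes, of Tsix, of the other genes without Tsix and of the H2-Q sum in CD4 and CD8 T-like barcodes were chosen only after the result was seen. Migratory dendritic cells, which carry antigen from the gut wall to the node, made up most myeloid-like barcodes (1169 in LysoPS-OVA, 2506 in free OVA, 1909 in citrate buffer). Against citrate buffer, LysoPS-OVA barcodes of this class carried less Aldh1a2 (0.637 times, 0.581 to 0.699), less Ebi3 (0.534 times) and less of the costimulatory ligand Cd70 (0.292 times, and 0.680 among whole-cell-like barcodes, 0.261 to 1.60), and more Relb, a factor of dendritic cell maturation (1.43-fold), Rgs1 (1.52-fold) and Dnajb1 (1.77-fold). MHC class II genes were higher (0.15 log2; H2-Ab1 1.31-fold) and cell cycle genes lower (-0.92 log2, all 7 members). Interferon response genes were lower (-0.29 log2; Isg15 0.597 and Ifi27l2a 0.501 times) although Usp18 was 1.73 times as high, and among whole-cell-like barcodes the median was 0.15. Against free OVA, where the all-gene median was 0.16 log2, Cd86 was 2.07 times as high (1.66 to 2.59), Nfkb1 1.69 times (1.42 to 1.99), Aldh1a2 0.716 times and Il4i1 0.785 times. Free OVA barcodes carried 0.523 times the Cd86 and 1.37 times the Il4i1 of citrate buffer, with an all-gene median of -0.26 log2. The tolerogenic list was not apart from matched lists in any of the 3 comparisons (-0.06, -0.03 and -0.12 log2).

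Small clusters marked by interferon response genes were found in both B and T cells. The B-like one (Ifit3, Usp18, Ifit1) held 5.22% of B-like barcodes in LysoPS-OVA (4.67 to 5.81), 5.30% in free OVA (4.68 to 5.99) and 2.66% in citrate buffer (2.27 to 3.11). The T-like one (Ifit1, Isg15, Iigp1) held 1.94% (1.59 to 2.33), 2.56% (2.03 to 3.18) and 1.16% (0.939 to 1.43) of T-like barcodes. An activated B-like cluster (Egr3, Ccl4, Cd83) held 1.16%, 1.08% and 1.25% of B-like barcodes, within counting error of each other. Of kept barcodes, macrophage-like ones (C1qa, Lyz2) were 0.778% in LysoPS-OVA, 2.09% in free OVA and 1.40% in citrate buffer, conventional DC 2-like 0.251%, 0.208% and 0.527%, and plasmacytoid DC-like 0.132%, 0.088% and 0.25%. The unnamed shallow cluster nearest to the conventional DC 2 list, outside these shares, held 1.88%, 4.50% and 1.84%. Genes given here for clusters are among their 10 leading genes and were chosen after their values were seen.

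Barcodes low in Malat1 were most frequent in free OVA. Within migratory dendritic cell-like barcodes, genes over 100 kb were lower than genes under 10 kb in low-Malat1 against whole-cell-like barcodes, by -0.91 log2 in the library nearest to 0, which is in line with cytoplasm without a nucleus. Depth alone is argued against from 1500 UMIs up: among barcodes of 1500 to 3000 UMIs 72.6% were low in Malat1 in free OVA, 1.79 times the higher of the other 2 libraries. From 3000 to 6000 UMIs the share was 21.7% in free OVA, 9.88% in citrate buffer and 5.04% in LysoPS-OVA. Below 1500 UMIs free OVA and LysoPS-OVA were close. Their shares were 82.0% and 77.4% from 1000 to 1500 UMIs (citrate buffer 48.9%), and 65.3% and 70.0% from 500 to 1000 (citrate buffer 38.8%). Class makeup was not matched. The early response and heat shock genes, higher in LysoPS-OVA than in citrate buffer, are not explained by more low-ribosomal barcodes in citrate buffer, since among whole-cell-like barcodes the lowest median of the 5 classes was 0.24 log2. A stress shared by the whole suspension stays open: the median was 0.653 log2 in NK-like, 0.589 in germinal centre B-like and 0.316 in plasma-like barcodes, but -0.049 (-0.151 to 0.109) in cycling and -0.29 (-0.802 to 0.02) in fibroblast-like ones. The bound set beforehand against it, at or below 0 in at least 2 of the 5, was met in name, but both values lay within counting error, and asking for the interval as well was added after the result was seen.

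Xist was lower in LysoPS-OVA than in citrate buffer in 4 classes, and 8 of 4203 tested genes differed alike in all 4 by at least 0.6 log2, a threshold set when the test was written (Vmn2r96, Dnaja1, Dnajb1 and Lncpint higher; Cmss1, Tsix, AY036118 and Top2a lower). For Xist, which is not among the 8, a different sex makeup of the pools may be the source, since summed Y-linked genes were at least 1.29 times as high in LysoPS-OVA in each class, and 87.6% of B-like barcodes with transcripts of a single sex carried Y-linked ones against 53.9% in citrate buffer. For the 7 genes other than Tsix it is argued against: in barcodes with Y-linked and no Xist UMIs their median shift was 1.01 log2 in B-like (0.823 to 1.19), 0.972 in CD4 and 0.918 in CD8 barcodes, and in myeloid-like ones 0.76 of the shift was left (0.632 log2, 0.437 to 1.08). For Tsix, antisense to Xist, it stays open, since 0.195 of the shift was left in B-like, 0.583 in CD4, 0.235 in CD8 and 1.1 in myeloid-like barcodes, the last from 3 UMIs. For H2-Q7, counts moved from the other counted copies are argued against, since the sum of 6 H2-Q genes was at least 2.07 times as high in CD4 (1.98 to 2.17) and CD8 T-like barcodes (2.17, 2.03 to 2.31), and without H2-Q7 still 1.19 and 1.51 times. The sum is mostly H2-Q7: without it 74.7 of 368.6 CPM were left in CD4 T-like barcodes of LysoPS-OVA. Reads assigned to no single copy are outside the sum, so a change in those was not tested. The bound set beforehand asked for a higher sum in B-like and myeloid-like barcodes too, where H2-Q7 is not part of the pattern and the sums were 1.1 and 1.30. Treatment and library are the same split here, so an effect of the feeding was not tested apart from one of the pool or the preparation. The wording of the Xist pattern and the parting of Tsix from the other genes came after the results.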
